A study of Mus musculus with 4 samples.

How the data were processed

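Kidneys of C57BL/6 mice at week 22 were profiled by single-nucleus RNA sequencing in 4 libraries, 2 from untreated kidneys and 2 from kidneys treated with losartan, a blocker of the angiotensin II type 1 receptor. Per the labels, tissue was flash-frozen, nuclei were released with an isolation kit, and libraries were made with 10x Genomics Chromium chemistry on Chip G. Dose, route and length of the treatment, the sex of the mice and the hour of tissue collection are not given in the sources used here. The replicates are separate libraries, and no label says that they come from separate animals. The p-values below therefore measure the spread between these samples, part of which may be technical.

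The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, and per the file headers they were written by Cell Ranger 5.0.0. The submitters' processing notes name the mouse build mm10 and Bowtie 0.12.2 without a role for either. Each matrix lists the same 27998 genes, of which 27722 were placed on GRCm38 (mm10) with GENCODE M21 by gene identifier. Symbols carried by more than 1 gene, 56 in all, were told apart by identifier. The strand used in counting is not stated, so values of genes that overlap another gene on the opposite strand are uncertain.

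Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes. Doublets were scored per library with the Scrublet method of scanpy 1.11.5. Where its automatic threshold marked under 0.5% of nuclei, as in untreated library 2 and losartan library 1, the highest scores were removed at 0.8% per 1000 nuclei instead. After this, 34828 of 39654 nuclei remained; 4366 were removed as doublets, 510 for mitochondrial UMIs and 0 for few UMIs or genes, a nucleus being counted under each reason that held for it. Normalisation to 10000 UMIs per nucleus, 3000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 0) gave 34 clusters, with no integration of the libraries. Clusters were named from 25 fixed sets of cell type markers. A name needed at least 3 markers detected in 10% of the nuclei and a mean score at least 0.25 above the next cell type. The score was log2 CPM after adding 5, standardised per gene across clusters. No other set could have more markers among the 10 leading genes of the cluster. Sets of the same lineage counted as 1 class where a cluster could not be split between them, and the proximal tubule segments were kept as 1 class, which departs from the plan of naming S1/S2 and S3 apart. Clusters not separated by these limits, or with a mitochondrial share above 5 times the median cluster, stayed unnamed. Class names stand for nuclei that resemble that cell type by its markers, with the suffix "-like" left out. In all, 28 clusters with 32567 nuclei received 18 class names, and 6 clusters with 2261 nuclei stayed unnamed.

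Raw counts were summed per library over all kept nuclei, for the whole kidney, and over each of the 12 named classes with at least 50 nuclei in every library. Losartan was compared with untreated by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and the filterByExpr filter, 1 fit per class. P-values were adjusted by Benjamini-Hochberg (BH) within each fit, and adjusted p under 0.05 is written as a call. Fold changes are log2, losartan over untreated, and levels are counts scaled by edgeR to a common library size (CPM), given as mean ± SD of 2 libraries. Shares of nuclei were tested with the same edgeR test on nuclei per class with the library total as offset. An exact two-sided permutation test of 2 libraries against 2 cannot go below p = 0.333, and by chance 33.3% of genes have both losartan libraries beyond both untreated libraries. Intervals on shares of single libraries are 95% Clopper-Pearson intervals, and a count of 0 allows up to 3 counts; both cover counting error only. The difference between the losartan effects in the proximal tubule and the thick ascending limb, the most abundant classes of their kinds, was tested in edgeR with library as a block.

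Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within the whole kidney or a class, for lists with at least 5 tested members. Counts of list members "adjusted over the list alone" use the same p-values with BH over the members. The lists, the cell type markers, the tests and the rule for naming genes were chosen before the data were examined. The 26 lists cover the renin-angiotensin system, vasoactive signalling, sodium and water transport, corticosteroid-responsive genes, proximal tubule transport, fatty acid oxidation, gluconeogenesis and amino acid metabolism, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, cholesterol synthesis, extracellular matrix and fibrosis, TGF-beta signalling, podocyte and glomerular basement membrane, tubule injury, inflammation and antigen presentation, interferon response, oxidative stress response, unfolded protein response, hypoxia, immediate early and heat shock genes, circadian clock, cell cycle, cytosolic ribosomal proteins, sex-dimorphic genes, nuclear-retained RNA, and abundant proximal tubule transcripts as a sign of free RNA. The rule named every measured member of the renin-angiotensin list in the whole kidney, with Ren1 and Agtr1a also in mural nuclei. It named the genes with the largest fold change among calls with a mean CPM of at least 10 and both losartan libraries beyond both untreated ones, 10 each way in the whole kidney and the most abundant class and 5 each way in other classes. Where fewer than 3 genes passed, the 3 each way with the smallest p were given as values. For each called list it named 2 to 4 members with the smallest p. Predicted genes and pseudogenes were counted and not named. Genes outside the rule are said to have been chosen after their values were seen. Some members of the gene lists that the rule selects are not reported here.

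The pipeline was tested on simulated data with 200 changed genes at log2 changes of 1 and 2, and the recovered percentages are given with the results. Alternatives covered other normalisations (DESeq2 1.42.0 size factors, no composition factor, upper quartile), other gene and nucleus filters, doublets kept, nuclei thinned to 1000 UMIs, other clustering resolutions, genes centred within libraries, a replicate block, an estimated inter-gene correlation, the rotation test fry, and each library left out in turn. With 1 library left out, the lone sample is assumed to vary like the other group. Alternatives added after seeing the data were a common doublet rate, an upper limit of 10000 UMIs, clustering without the called genes, the proximal tubule left out of the total, segments of the proximal tubule apart, leaving out genes or nuclei by their proximal tubule RNA, and leaving libraries out of the class by treatment test. The remaining tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.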

Results

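Transcripts were counted in 39654 barcoded nuclei from 4 mouse kidney libraries, 2 untreated and 2 treated with losartan. Total counts were 42290414 and 54971880 UMIs in untreated libraries 1 and 2, and 58820323 and 59078762 UMIs in losartan libraries 1 and 2. After filtering, the libraries held 8374, 8993, 9020 and 8441 nuclei in the same order, with median depths of 3340.5, 4095, 4227.5 and 3844 UMIs. The comparison asks which cell classes and which transcripts differ between losartan-treated and untreated kidneys. Losartan blocks the receptor through which angiotensin II raises blood pressure and drives fibrosis.

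The first question was whether the mix of cell classes differed. Proximal tubule nuclei, from the segment that reabsorbs most of the filtrate, made up 27.4 ± 7.32% of nuclei in untreated and 44.4 ± 7.56% in losartan libraries (SD, n = 2). Injured proximal tubule nuclei, named from markers such as Havcr1 and Vcam1, made up 4.83 ± 0.774% and 0.993 ± 0.824%. Macrophages and dendritic cells held 3.27 ± 1.10% and 1.10 ± 0.0595%, lymphocytes 2.17 ± 1.27% and 0.505 ± 0.0237%, endothelium 9.14 ± 1.24% and 4.91 ± 2.07%, and mural and mesangial nuclei 1.55 ± 0.297% and 0.860 ± 0.0403%. Podocytes held 1.89 ± 0.141% and 1.33 ± 0.143%. Thick ascending limb nuclei, at 12.2% and 11.5%, and distal convoluted tubule nuclei, at 7.65% and 7.13%, lay closer together. With the proximal tubule left out of the total, the mean shares were 2.61% and 2.40% for podocytes, 12.6% and 8.67% for endothelium and 2.12% and 1.56% for mural and mesangial nuclei. None of these shares passed the test. The edgeR test called 0 of 24 classes and unnamed clusters, with 3 at an unadjusted p under 0.05. The limma test on arcsine square root shares called 0, with 4 at an unadjusted p under 0.05. The log2 changes were -1.58 for macrophages and dendritic cells (adjusted p = 0.243), -2.28 for injured proximal tubule (adjusted p = 0.298) and 0.70 for proximal tubule (adjusted p = 0.354), each with both losartan libraries on the same side of both untreated libraries. The exact two-sided permutation test cannot go below p = 0.333 here, and a 4-fold change in simulated shares was recovered in 3 of 100 draws. In losartan library 1 the injured proximal tubule share was 0.410% (95% Clopper-Pearson interval 0.289 to 0.565). That library also gave 1221 of the 1254 nuclei of 1 proximal tubule cluster and 322 of the 386 nuclei of another. Markers of macula densa, lymphatic endothelium, neutrophils, erythroid cells and adrenal cortex named no cluster. Schwann nuclei were seen at 0 of 8441 in losartan library 2, which allows a share of up to 0.0355%.

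**Figure D1:**
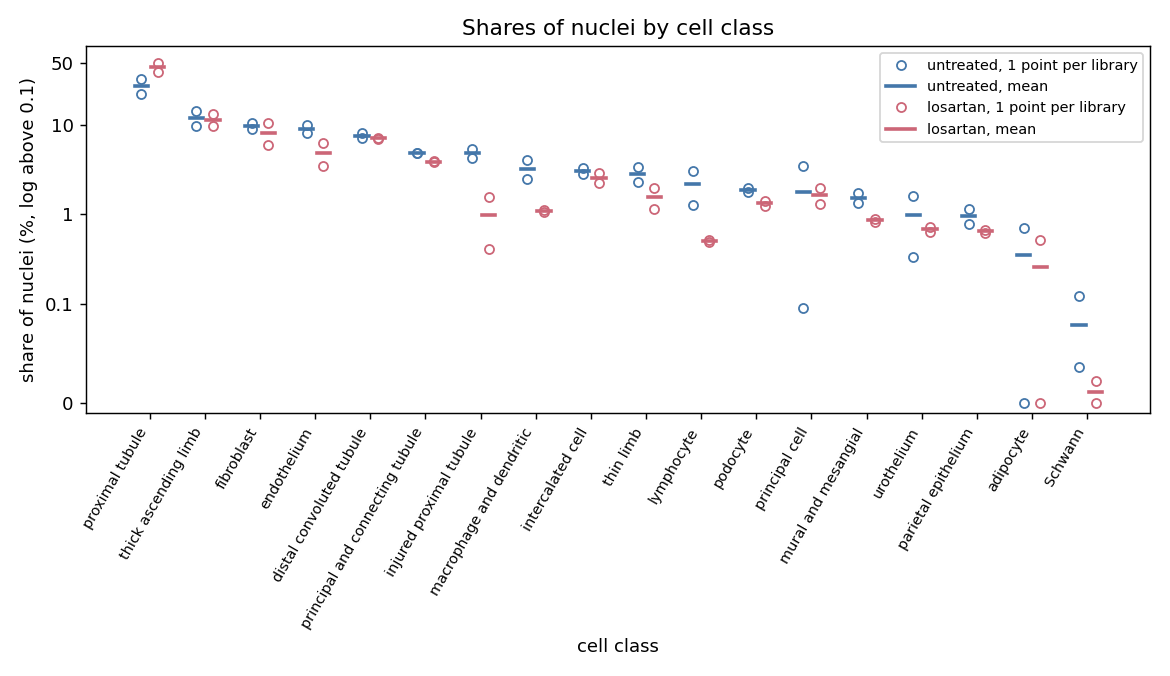
Share of nuclei (%, logarithmic above 0.1) for each named cell class, with 1 open point per library and a bar at the mean of the 2 untreated or the 2 losartan libraries. Proximal tubule averages 27.4% untreated and 44.4% with losartan, and injured proximal tubule 4.83% and 0.993%, with no share past the test.

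The second question was which genes differ in the kidney as a whole. No single gene passed, and the renin-angiotensin system, the pathway losartan acts on, gave values on both sides of 0. Ren1 (ENSMUSG00000070645, chromosome 1, 133350510 to 133360325, GRCm38), which encodes renin, stood at 13.7 ± 0.0708 CPM untreated and 16 ± 4.18 with losartan (log2 0.23, adjusted p = 0.588), and at -0.07 without losartan library 1. Agt (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), which encodes angiotensinogen, stood at 8.74 ± 1.49 and 4.0 ± 0.675 CPM (log2 -1.12, adjusted p = 0.162). Agtr1a (ENSMUSG00000049115, chromosome 13, 30336441 to 30382867), the receptor that losartan blocks, stood at 77.0 ± 7.92 and 108 ± 19.4 CPM (log2 0.49, adjusted p = 0.225). The log2 values were 0.50 for Ace, -0.61 for Agtr1b and -0.21 for Mas1. They were 0.17 for Enpep, 0.01 for Mme, 0.13 for Anpep, -0.07 for Lnpep, -0.09 for Atp6ap2 and -0.05 for Nr3c2, and Agtr2 was too low to test. In mural and mesangial nuclei, where renin cells belong, Ren1 stood at 563 ± 92.8 and 519 ± 244 CPM (log2 -0.11, adjusted p = 0.938) and Agtr1a at 607 ± 133 and 536 ± 155 CPM (log2 -0.18, adjusted p = 0.861). The genes with the smallest p were Cyp2d12, a cytochrome P450 (59.8 ± 4.66 and 142 ± 2.65 CPM, log2 1.25), Map3k7cl (1.03) and the carboxylesterase Ces1d (1.02) on the higher side. On the lower side they were Prex1 (-1.16), Dcdc2a (87.1 ± 7.99 and 30.3 ± 5.24 CPM, -1.52) and the lymphoid transcription factor Pou2f2 (-1.37), and all 6 had adjusted p = 0.157. The edgeR test called 0 of 18225 genes, with 3449 at an unadjusted p under 0.05, while DESeq2 called 1227 (537 higher and 690 lower with losartan). Losartan and untreated libraries did not overlap for 54.1% of genes, against 33.3% by chance. Without losartan library 2 edgeR called 22 genes, and without any other library 0. On simulated whole-kidney data the edgeR test found 59% of genes changed by a log2 of 1.

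Within cell classes edgeR made 151 calls, 81 higher and 70 lower with losartan, on 118 distinct genes, and none of the 20 genes called in more than 1 class changed sign. Kap, an androgen-driven transcript of the proximal tubule, rose in 6 classes, with log2 changes of 1.5 to 2.03. Spp1, which encodes osteopontin, a secreted protein that injured tubules make, fell in 3 classes (log2 -1.85 to -1.37) and was lower in all 12. Sntg1, a syntrophin that anchors membrane proteins, fell in 3 classes (-3.83 to -1.85). The xenobiotic enzymes Acsm2 (4 classes), Cyp2e1 (3) and Cyp4b1 (3) rose. Of the 80 higher calls outside the proximal tubule, 61 were on genes with a higher level in the proximal tubule than in the class that called them, against 9 of 69 lower calls. Against the class with the highest level, whichever it was, 66 of 81 higher and 59 of 70 lower calls were on genes held at under 50% of that level in the class that called them. The share over all tested genes was not measured, so these counts do not set the calls apart from other genes. Transcripts of the proximal tubule moved with treatment in other classes: its 306 most specific genes had a median log2 change of 0.54 in those classes and 0.65 in the whole kidney. Kap UMIs were found in 84.2% to 92.9% of the nuclei of other classes in untreated and in 98.9% to 100% in losartan libraries, at the median depths given above. These classes should lack Kap, so its detection in a nucleus is read as background. In simulated data 0.847% (podocytes) to 15.9% (proximal tubule) of the calls in a class fell on genes left unchanged. Counts of calls depended on the library left out, at 120 without losartan library 1, 1070 without losartan library 2, 4023 without untreated library 1 and 1695 without untreated library 2.

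Distal nephron nuclei showed more Egf. Egf (ENSMUSG00000028017, chromosome 3, 129677565 to 129755316), a growth factor made by these segments that acts on tubule repair and magnesium uptake, rose in the distal convoluted tubule from 1920 ± 116 to 4579 ± 480 CPM (n = 2, log2 1.25, edgeR adjusted p = 0.00279). In the thick ascending limb it rose from 4157 ± 596 to 9191 ± 339 CPM (log2 1.14, adjusted p = 0.0283), and it was higher with losartan in 12 of 12 classes. The Egf level in the distal convoluted tubule was 48.8% of that in the thick ascending limb. Rises outside the thick ascending limb were not tested apart from RNA of that segment. Egf was chosen after its values were seen, and Gm42697, which lies on the opposite strand inside it (chromosome 3, 129728845 to 129740188), was called beside it (log2 1.2 in the thick ascending limb). The salt transporters and the secreted glycoprotein that mark these segments were not called: Slc12a3 had a log2 change of 0.23 in the distal convoluted tubule, and the transporter Slc12a1 0.25 and Umod, which encodes uromodulin, 0.26 in the thick ascending limb.

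In the distal convoluted tubule, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) fell from 591 ± 255 to 165 ± 12.1 CPM (log2 -1.84, adjusted p = 0.0329). Dcdc2a (ENSMUSG00000035910, chromosome 13, 25056004 to 25210706), a doublecortin-domain gene used here as a marker of injured tubule, fell from 203 ± 36.8 to 19.8 ± 10.1 CPM (log2 -3.37, adjusted p = 0.00253). Sntg1 (-2.34), Sntg2 (-2.21) and Sgcd (-1.96), all part of the dystrophin-associated complex, fell too. Relative to the class with the highest level, the level here was 1.16% for Sntg1 (fibroblasts), 11.1% for Sntg2 and 9.52% for Sgcd (both adipocytes). It was 12.2% for Spp1 (urothelium) and 19.0% for Dcdc2a (parietal epithelium). These falls were not tested apart from RNA of those classes. Adipocyte nuclei numbered 0 and 64 in untreated libraries 1 and 2, and 0 and 44 in losartan libraries 1 and 2. In the same order Sgcd stood at 225, 190, 55.3 and 51.4 CPM here, and Sntg2 at 17.3, 21.2, 4.19 and 4.08. These levels did not follow the adipocyte nuclei, which argues against RNA of adipocytes as the source for Sgcd and Sntg2 here. Etv4, given below, had its highest level in the distal convoluted tubule. Grin3a (ENSMUSG00000039579, chromosome 4, 49661611 to 49845744), a glutamate receptor subunit, rose from 14.6 ± 1.52 to 90.6 ± 2.92 CPM (log2 2.62, adjusted p = 0.000841), as did Zcchc16 (1.69). Kap (1.85), Acsm2 (1.54) and Ass1 (1.46) also rose, all at higher levels in the proximal tubule. Among genes chosen after their values were seen, Abca13, a marker of this segment, rose from 6498 to 10923 CPM (log2 0.75, adjusted p = 0.0329), Igfbp5 rose (1.44, adjusted p = 0.0104) and the growth factor response gene Etv4 fell (-1.21, adjusted p = 0.0329). In all, 34 of 12060 genes were called, 16 higher and 18 lower, with 6 and 16 calls without losartan library 1 or 2 and 767 and 262 without untreated library 1 or 2. Without losartan library 1 the adjusted p was 0.0662 for Kap, 0.131 for Acsm2, 0.553 for Ass1, 0.582 for Sntg1, 0.559 for Sntg2, 0.616 for Spp1, 0.25 for Abca13, 0.344 for Igfbp5 and 0.596 for Etv4. Without losartan library 2 it was 0.257, 0.123, 0.203, 0.181, 0.108 and 0.192 for Ass1, Sntg1, Sntg2, Spp1, Igfbp5 and Etv4. Egf, Grin3a, Dcdc2a and Sgcd kept their calls without either.

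In the thick ascending limb 34 of the 35 lower calls were on genes held at under 50% of their level in another class. The share over all genes tested there was not measured. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine that draws T cells, fell from 36.3 ± 13.7 to 5.58 ± 3.20 CPM (log2 -2.65, adjusted p = 0.0407). The inflammatory caspase Casp4 (-2.41), the leukotriene synthase Ltc4s (-2.17), Xkr4 (-3.00) and Ctnnd2 (-2.55) fell with it. Spp1 (-1.37) fell, and so did Cp, the copper carrier ceruloplasmin (61.2 to 23.1 CPM, -1.40, adjusted p = 0.0196), and Il34, a growth factor for macrophages (239 to 134 CPM, -0.84, adjusted p = 0.0283). Relative to the class with the highest level, the level here was 48.4% for Cxcl10 and 23.2% for Il34 (injured proximal tubule), 8.67% for Casp4 (fibroblasts) and 1.92% for Cp (parietal epithelium). Inmt (2.22), Cyp2e1 (2.03), Kap (557 ± 108 to 2272 ± 157 CPM, 2.03), Dnase1 (1.65) and Acsm2 (1.58) rose. In all, 54 of 13215 genes were called, 19 higher and 35 lower. No call was left without losartan library 1 or losartan library 2. There the adjusted p of the 10 genes named by the rule was 0.465 to 0.710 and 0.234 to 0.363, that of Egf 0.465 and 0.263, and those of Cp, Spp1 and Il34 0.465, 0.620 and 0.512 and 0.267, 0.363 and 0.263. By contrast, 952 and 529 genes were called without untreated library 1 or 2.

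The collecting system had fewer calls. In principal cell and connecting tubule nuclei 12 of 10785 genes were called, 7 higher and 5 lower. Inmt (2.22), Kap (1.93), Cyp4b1 (1.84), Cyp2e1 (1.77) and Acsm2 (1.49) rose, and Spock3, a proteoglycan gene chosen after its values were seen, rose from 59.6 to 162 CPM (log2 1.44, adjusted p = 0.00384). The synaptic adhesion gene Nlgn1 (-2.06), the antisense transcript Junos (-1.68, of uncertain strand), Prom1 (-1.0), a marker of tubule progenitors, and the antiviral gene Apobec3 (-0.88) fell. Relative to the class with the highest level, the level here was 7.32% for Nlgn1 (endothelium) and 17.6% for Junos (urothelium). It was 45.2% for Apobec3 (principal cells) and 57.4% for Prom1 (thick ascending limb). The count was 52, 156, 535 and 207 without losartan library 1, losartan library 2, untreated library 1 and untreated library 2. In intercalated cells, which secrete acid or base, 0 of 10128 genes were called by edgeR, with 1188 at an unadjusted p under 0.05 and 189 called by DESeq2. The smallest p there belonged to Cyp2j13 (log2 2.71), Kap (1.70) and Fmo2 (1.95), and to Srgap1 (-1.64), the glucose transporter Slc2a1 (-1.97) and Junos (-1.29). All had adjusted p of 0.0782 to 0.0797. In losartan library 1, 59 of 265 intercalated nuclei (22.3%) held over 5% of their UMIs from proximal tubule genes, against 1.95% to 3.16% in the other libraries. Without such nuclei the median log2 change of proximal tubule genes there went from 1.63 to 0.46. The intercalated count was 0, 229, 304 and 129 without losartan library 1, losartan library 2, untreated library 1 and untreated library 2. In the thin limb edgeR called 0 of 8303 genes (219 at an unadjusted p under 0.05, 3 by DESeq2). Log2 values there were 1.84 for Kap, 1.82 for Slc5a12, 2.15 for Cyp2e1, -1.57 for Spp1, -1.25 for Ranbp3l and -1.16 for Dcdc2a, and 237 and 170 calls without untreated library 1 or 2.

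In the glomerulus, podocytes, the cells of the filtration barrier, showed lower Sema3g, Nupr1 and Plod2. Sema3g (ENSMUSG00000021904, chromosome 14, 31217860 to 31230352), a semaphorin that podocytes secrete, fell from 869 ± 14.9 to 492 ± 26.9 CPM (log2 -0.82, adjusted p = 0.0355). The stress-response gene Nupr1 (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861) fell from 367 ± 76.7 to 106 ± 20.2 CPM (log2 -1.78, adjusted p = 0.00418). The collagen-modifying enzyme Plod2 (1420 ± 131 to 705 ± 105 CPM, -1.01), Igfbp7 (2144 ± 305 to 1206 ± 43.8 CPM, -0.83) and the receptor Erbb4 (-0.71) fell as well. Sema3g and Plod2 had their highest level in podocytes. Relative to the class with the highest level, the podocyte level was 11.1% for Erbb4 (thick ascending limb). It was 68.6% for Nupr1 (principal cells) and 75.7% for Igfbp7 (fibroblasts). The rising genes Ugt2b38 (2.38), Cyp2j13 (2.33), Cyp2e1 (2.10), Kap (1.95) and Fbxl7 (1.63) include enzymes that the proximal tubule holds at a higher level. The test called 16 of 6406 genes, 9 higher and 7 lower, in 329 untreated and 232 losartan nuclei. Without the 10% of nuclei richest in proximal tubule UMIs only Kap and Nupr1 kept their calls, the adjusted p being 0.0527 for Plod2 in podocytes, 0.0880 for Sema3g and Igfbp7 and 0.156 for Erbb4. Without losartan library 1 only Kap kept its call. The adjusted p was then 0.0882 for Nupr1, 0.592 for Sema3g, 0.327 for Plod2, 0.426 for Igfbp7, and 0.687 to 0.783 for Erbb4, Fbxl7, Cyp2e1, Cyp2j13 and Ugt2b38. In turn 73, 183 and 63 genes were called without losartan library 2, untreated library 1 and untreated library 2. In parietal epithelium Kap rose (712 ± 158 to 2275 ± 227 CPM, log2 1.69, adjusted p = 0.00530), the 1 call among 4801 genes. There Cyp2e1 had 2.98, Cyp4b1 1.99, Spp1 -1.26 (adjusted p = 0.0542), Fmn1 -0.91 and Adamts5 -1.35. Parietal epithelium had 15, 36, 64 and 14 calls without losartan library 1, losartan library 2, untreated library 1 and untreated library 2.

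In mural and mesangial nuclei, the contractile cells of vessels and glomeruli, Spp1 fell from 447 ± 165 to 124 ± 21.3 CPM (log2 -1.85). Csmd1, a complement inhibitor, fell from 865 to 175 CPM (-2.30), and Sntg1 fell (-3.83). Relative to the class with the highest level, the level here was 9.64% for Csmd1 and 2.96% for Sntg1 (both fibroblasts). It was 9.17% for Spp1 (urothelium). These falls were not tested apart from RNA of those classes. Epha6 (4.12, adjusted p = 0.0289), the organic anion transporter Slco1a1 (3.64), Ldhd (2.69), Cyp4b1 (2.32) and Acy3 (2.30) rose, and 26 of the 28 higher calls were on genes held at a higher level in the proximal tubule. Nuclei with over 5% of their UMIs from proximal tubule genes numbered 16 of 75 in losartan library 1 and 9 of 75 in losartan library 2, against 9 of 112 in untreated library 1 and 3 of 158 in untreated library 2. The test called 32 of 7076 genes, 28 higher and 4 lower, against 5 at resolution 0.5 and 0 at resolution 2, without nuclei above 10000 UMIs, without the 10% of nuclei richest in proximal tubule UMIs, and without genes at a higher level in the proximal tubule. Without losartan library 1 the adjusted p was 0.173 for Epha6, 0.414 for Ldhd and 0.162 for Acy3, and the counts were 298, 359 and 156 without losartan library 2, untreated library 1 and untreated library 2.

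Fibroblasts, endothelium and macrophages had no call by edgeR. Fibroblasts had 0 of 13016 genes called (1042 at an unadjusted p under 0.05, 87 by DESeq2). Their values were -1.83 for Smoc2, a matrix protein linked to fibrosis, -2.02 for Kirrel3 (both adjusted p = 0.0572), -4.18 for Trhde, 3.15 for Cacng4, 1.81 for Kap and 1.80 for Cyp2e1. Endothelium had 0 of 11534 (605 at an unadjusted p under 0.05, 16 by DESeq2). Its values were 1.82 for Kap, 1.18 for Cyp4b1, 1.62 for Acsm2, -1.37 for the organic anion transporter Slco1a4, -0.72 for Fstl1 and -0.90 for Naip2. Macrophages and dendritic cells had 0 of 8157 (845 at an unadjusted p under 0.05, 13 by DESeq2). Their values were -2.28 for the lipid carrier Apoe (2054 and 423 CPM), -1.97 for Ms4a7, -3.25 for St18, 1.69 for Kap, 2.74 for Pir and 2.27 for Cyp2j13. Endothelial calls numbered 2, 335 and 156 without losartan library 2, untreated library 1 and untreated library 2, and fibroblast calls 287 and 9 without untreated library 1 and untreated library 2.

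In the proximal tubule, the largest class with 4722 untreated and 7791 losartan nuclei, Uroc1 (ENSMUSG00000034456, chromosome 6, 90333284 to 90364551), urocanate hydratase of histidine breakdown, fell from 62.8 ± 1.22 to 20.3 ± 0.549 CPM (log2 -1.63, adjusted p = 0.0487). The other call, the antisense transcript 0610031O16Rik, chosen after its values were seen, rose from 24.5 ± 2.73 to 94.9 ± 0.293 CPM (1.95, adjusted p = 0.0487). Values that did not pass included Smarca2 (1.48), Acvr2b, an activin receptor (1.16), the TGF-beta-inducible Klf10 (1.10), Ugt1a10 (-4.46) and Ano4 (-1.75). Male-type genes of this segment lay above 0 without a call: Slco1a1 2.72, Cyp4a12a 2.30, Cyp2e1 1.23, Kap 1.02 and Nudt19 0.88, while the female-type Slc7a12 had -1.42 and Prlr -1.81 (-0.82 and -1.19 without losartan library 1, -2.42 and -2.87 without losartan library 2). The test called 2 of 15036 genes, with 1810 at an unadjusted p under 0.05 and 295 called by DESeq2. In simulated data it found 91% of changes of a log2 of 1. The simulated genes varied independently, without differences between libraries shared across genes, so this does not bound the changes missed here. With segments apart Uroc1 had a log2 change of -0.54 in S1/S2 nuclei (edgeR adjusted p = 0.646), -1.05 in S3 nuclei and -1.77 in nuclei of neither segment, and was called in none of them. Without untreated library 1 and untreated library 2 no gene was called, with adjusted p of 0.0812 and 0.143 for Uroc1 and 0.0738 and 0.143 for 0610031O16Rik. The call for Uroc1 in proximal tubule nuclei also ended with resolution 0.5 (adjusted p = 0.0503), upper quartile factors (0.0551), genes centred within each library (0.0615), no mitochondrial limit (0.0626), nuclei thinned to 1000 UMIs (0.0647), a mean CPM of at least 10 (0.0715), doublets kept (0.177), the same doublet rate in every library (0.0714) and clustering without the called genes (0.0529). All of these except thinning also ended the call for 0610031O16Rik, at the same adjusted p. In contrast, 19 and 260 genes were called without losartan library 1 and losartan library 2.

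**Figure D2:**
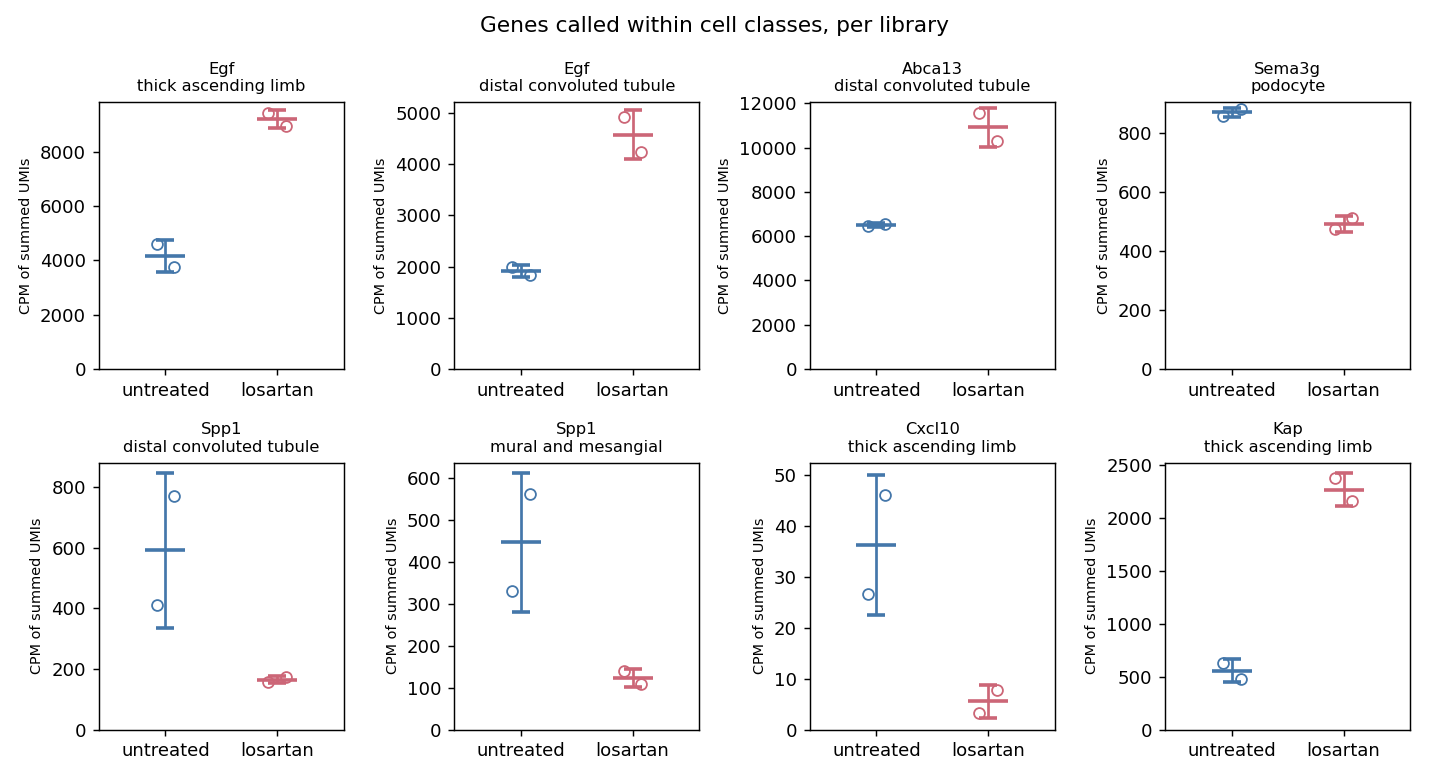
CPM of summed UMIs for 8 called gene and class pairs, untreated and losartan on the horizontal axis, with 1 open point per library and a bar and whiskers for mean and SD (n = 2). Egf in the thick ascending limb goes from 4157 to 9191 CPM, Spp1 in the distal convoluted tubule from 591 to 165 CPM and Kap in the thick ascending limb from 557 to 2272 CPM.

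The gene lists asked which programmes moved together. Tubule injury genes, made by damaged epithelium, fell in the whole kidney and in all 12 classes by camera, with a median log2 change of -1.0 in the whole kidney (adjusted p = 1.21e-09; adjusted p = 0.482 with an estimated correlation). In the whole kidney 6 of 18 members were lower adjusted over the list alone and 0 over all genes. The values were -1.48 for Spp1, -4.31 for Lcn2, the neutrophil gelatinase-associated lipocalin, -1.73 for Cd44 and -2.01 for Sox9. In the proximal tubule the median was -0.95 (adjusted p = 0.334 with an estimated correlation), 10 of 17 members were lower adjusted over the list alone, and Havcr1, the injury marker KIM-1, had -1.65, Itgb6 -1.05 and Sox9 -3.07. In the distal convoluted tubule the median was -1.19 (adjusted p = 0.254 with an estimated correlation), with 10 of 14 lower adjusted over the list alone and 2 over all genes. In the thick ascending limb it was -0.77 (adjusted p = 0.195 with an estimated correlation), with 8 of 15 lower adjusted over the list alone and 3 over all genes. These medians kept their call with each library left out. In fibroblasts the call was lost without untreated library 2 (-0.04, adjusted p = 0.0502). In macrophages and dendritic cells the median, -0.15, lost its call without untreated library 1 (adjusted p = 0.208) and losartan library 1 (adjusted p = 0.117).

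Inflammation and antigen presentation genes fell in the whole kidney (median -0.98, adjusted p = 3.86e-11; adjusted p = 0.482 with an estimated correlation) and in 11 of 12 classes. In the whole kidney 10 of 20 members were lower adjusted over the list alone and 0 over all genes, among them the class II genes H2-Ab1 (-1.10), H2-Eb1 (-1.24) and H2-Aa (-1.17) and the cytokine gene Tnf (-2.66). The median was -0.58 in the proximal tubule (adjusted p = 0.363 with an estimated correlation), with Ccl2, which draws monocytes, at -2.28, Relb at -1.02 and B2m at -0.64. The 12 calls of this list became 10 without untreated library 2 and 9 without losartan library 1. Interferon response genes fell in the whole kidney (median -0.70, adjusted p = 7.67e-11; adjusted p = 0.564 with an estimated correlation) and in 7 of 11 classes. There 12 of 21 members were lower adjusted over the list alone and 0 over all genes, with the peptide transporter Tap1 at -0.87, Stat2 at -0.57, Rnf213 at -0.43 and Ifi44 at -0.86. In the thick ascending limb the interferon median was -0.62 (adjusted p = 4.04e-09; adjusted p = 0.195 with an estimated correlation), with Gbp2 at -2.96, Ifit1 at -1.73 and Isg15 at -1.66. Without untreated library 2 the interferon list fell in 5 of these 12 in place of 8. With every library at the mean class mix, the interferon median on log2 CPM went from -0.76 to -0.36, 47.5% of its size (30.9% to 66.7% with each library left out). Both lists move with the mean shares of macrophages and lymphocytes, 3.27% and 2.17% untreated and 1.10% and 0.505% with losartan.

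Extracellular matrix and fibrosis genes, a target of angiotensin II signalling, fell in the whole kidney (median -0.62, adjusted p = 3.81e-05; adjusted p = 0.630 with an estimated correlation). Col1a1 had -1.45, Timp1 -1.54, Cyr61 -0.94 and Col4a1 -0.57, and 0 of 26 members were lower adjusted over the list alone or over all genes. They fell in fibroblasts (median -0.51, adjusted p = 3.28e-11; adjusted p = 0.445 with an estimated correlation). There Col1a1 had -1.47, Mmp2 -1.41, Tnc -1.32 and Col5a2 -0.95, and 2 of 25 members were lower adjusted over the list alone and 0 over all genes. They also fell in podocytes (-0.69, adjusted p = 0.233 with an estimated correlation), where Ctgf had -1.38, Sparc -0.94 and Col1a2 -0.93. They fell in mural and mesangial nuclei (-0.65, adjusted p = 0.394 with an estimated correlation) and parietal epithelium (-0.20, adjusted p = 0.490 with an estimated correlation). In macrophages and dendritic cells they rose (0.72, adjusted p = 0.601 with an estimated correlation), where thick ascending limb and proximal tubule genes also had medians above 0 (0.63 and 0.79). With every library at the mean class mix, the whole-kidney median on log2 CPM went from -0.73 to -0.39, 53.6% of its size (41.3% to 68.2% with each library left out). The whole-kidney median was -0.36 without untreated library 2, -0.23 without losartan library 1 and -1.08 without losartan library 2. Without untreated library 2 the fibroblast median was -0.28, and the calls in mural and mesangial nuclei (-0.31, adjusted p = 0.101), parietal epithelium (0.03, adjusted p = 0.218) and macrophages (0.13, adjusted p = 0.861) were lost. Without losartan library 1 the parietal call was lost too (-0.16, adjusted p = 0.140). The parietal median was -0.48 without untreated library 1 and -0.73 without losartan library 2, and that of macrophages 1.47 without untreated library 1. While the mean share of podocytes went from 1.89% to 1.33% (log2 -0.51, not called), podocyte and glomerular basement membrane genes fell in the whole kidney (-0.46, adjusted p = 0.000111; adjusted p = 0.482 with an estimated correlation; -0.27 without untreated library 2), with 8 of 18 lower adjusted over the list alone and 0 over all genes. They fell within podocytes (-0.28, adjusted p = 1.82e-07; adjusted p = 0.305 with an estimated correlation), where Podxl had -0.61, Col4a3 -0.44 and the calcium channel Trpc6 -2.30. They also fell in the thick ascending limb (-0.17, adjusted p = 0.483 with an estimated correlation), with no call without untreated library 1 (adjusted p = 0.273), and rose in macrophages and dendritic cells (0.45, adjusted p = 0.601 with an estimated correlation). There the median was 0.68 without untreated library 1, and the call was lost without untreated library 2 (adjusted p = 0.265) and losartan library 1 (0.09, adjusted p = 0.326).

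Proximal tubule functions were higher in whole-kidney sums and in other classes, together with the proximal tubule transcripts described above. Proximal tubule transport genes rose in the whole kidney (median 0.64, adjusted p = 1.41e-10; adjusted p = 0.564 with an estimated correlation; 0.42 without untreated library 2) and in 11 of 12 classes, the exception being the proximal tubule itself. In the whole kidney 10 of 22 members were higher adjusted over the list alone and 0 over all genes. The lactate carrier Slc5a12 stood at 1.24, the phosphate carrier Slc34a3 at 1.5, the sodium-hydrogen exchanger Slc9a3 at 0.64 and Slc4a4 at 0.60. Gluconeogenesis and amino acid metabolism genes rose in the whole kidney (median 0.70, adjusted p = 3.56e-11; adjusted p = 0.482 with an estimated correlation; 1.15 without untreated library 1), with 10 of 16 higher adjusted over the list alone and 0 over all genes (Aadat 1.2, Miox 1.17, Pcx 0.75). Within the proximal tubule this list rose by a median of 0.15 (adjusted p = 0.0215; adjusted p = 0.673 with an estimated correlation), with 0.31 without untreated library 1 and no call without untreated library 2 (0.09, adjusted p = 0.636) or losartan library 2 (adjusted p = 0.113). Fatty acid oxidation genes, the main fuel pathway of this segment, rose in the whole kidney (0.31, adjusted p = 5.94e-06; adjusted p = 0.482 with an estimated correlation), with 5 of 22 higher adjusted over the list alone and 0 over all genes (Cd36 0.79, Slc25a20 0.63, Cpt2 0.58). That list was called in 11 of 13 tests, and in 6 without untreated library 2. With every library at the mean class mix, the whole-kidney medians on log2 CPM went from 0.50 to 0.11 for transport genes (21.8% of its size, 7.24% to 23.5% with each library left out), from 0.56 to 0.20 for gluconeogenesis and amino acid metabolism (35.7%, 33.5% to 40.6%) and from 0.16 to 0.10 for fatty acid oxidation (63.7%, 28.3% to 80.0%). Abundant proximal tubule transcripts, fixed as a sign of free RNA, rose in the whole kidney and in all 12 classes. Their median was 0.56 in the whole kidney (adjusted p = 1.71e-07; adjusted p = 0.482 with an estimated correlation), and 0.86, 0.37 and 0.30 without untreated library 1, untreated library 2 and losartan library 1. It was 1.13 in intercalated cells (0.67 without losartan library 1) and 0.02 in the proximal tubule. There the call was lost without untreated library 1 (adjusted p = 0.0566) and untreated library 2 (adjusted p = 0.0806). Sex-dimorphic genes rose in all 13 tests (0.23 in the whole kidney, adjusted p = 3.94e-06; adjusted p = 0.482 with an estimated correlation; 0.39 without untreated library 1), with Slco1a1 at 3.34, Cyp2e1 at 1.83, Kap at 1.47 and Nudt19 at 1.45. Medians ran from 0.02 to 0.45, and the list also holds female-type and Y-linked genes. In whole-kidney CPM without TMM factors, the female-type Prlr went from 207 and 110 untreated to 34.9 and 89.1 with losartan. In the same order Slc7a12 went from 198 and 92.9 to 39.7 and 93.2, and summed Y-linked genes from 572 and 575 to 574 and 609.

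**Figure D3:**
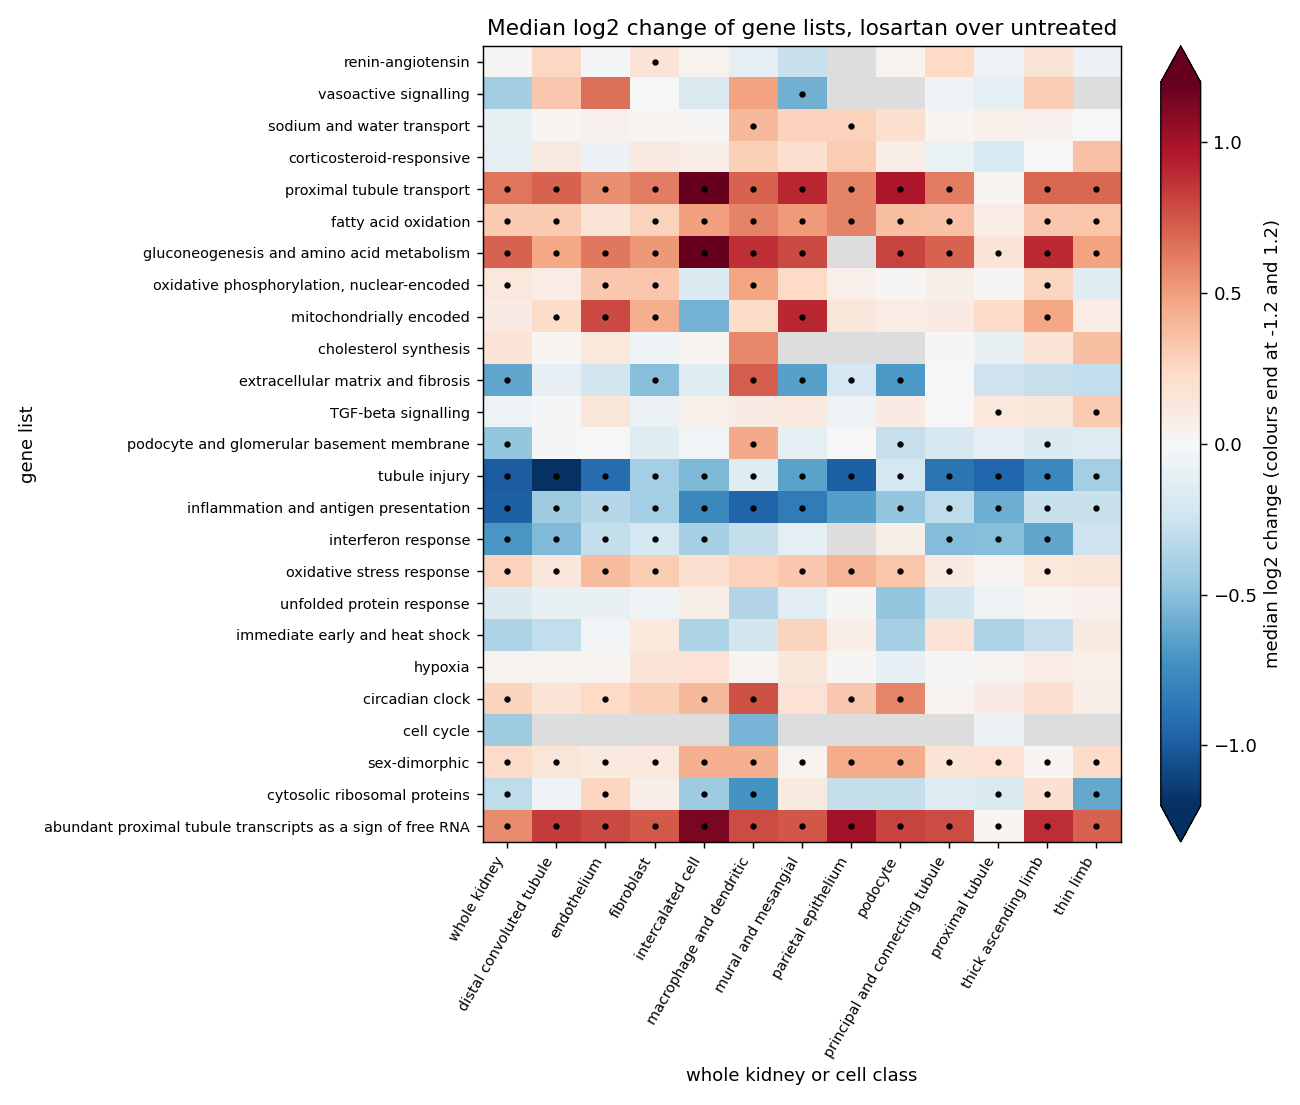
Median log2 change, losartan over untreated, of each gene list (vertical axis) in the whole kidney and in 12 cell classes (horizontal axis), with colours that end at -1.2 and 1.2, grey where fewer than 5 members were tested and a dot at each camera call. The tubule injury list lies below 0 in the whole kidney (-1.0) and in every class, and the proximal tubule transport list above 0 in the whole kidney (0.64).

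Among lists close to the action of losartan, the renin-angiotensin list was called in fibroblasts (median 0.15, adjusted p = 0.0357; adjusted p = 0.491 with an estimated correlation), with Agtr1a at 0.67 and Ren1 at 0.51, and not in the whole kidney (0.01, adjusted p = 0.856). That call was lost without untreated library 2 (-0.10, adjusted p = 0.748), losartan library 1 (-0.02, adjusted p = 0.152) and losartan library 2 (0.20, adjusted p = 0.114), and the median was 0.47 without untreated library 1. Vasoactive signalling genes fell in mural and mesangial nuclei (median -0.57, adjusted p = 0.00899; adjusted p = 0.394 with an estimated correlation), where the nitric oxide receptor subunits Gucy1a3 and Gucy1b3 had -0.84 and -0.69. This call was lost without untreated library 1 (adjusted p = 0.137), untreated library 2 (-0.32, adjusted p = 0.0916) and losartan library 1 (-0.34, adjusted p = 0.209). TGF-beta signalling genes rose in the proximal tubule (0.12, adjusted p = 0.0374; adjusted p = 0.562 with an estimated correlation), where Id1 (1.52), Id2 (0.60) and Id3 (1.53), targets of the BMP branch, had the smallest p. The TGF-beta median was 0.38 without untreated library 1, 0.21 without losartan library 2 and 0.08 without losartan library 1, with no call without untreated library 2 (adjusted p = 0.181). Sodium and water transport genes were not called in the whole kidney (-0.09, adjusted p = 0.990).

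With all 4 libraries several lists gave no call in any class or the whole kidney: corticosteroid-responsive genes (smallest adjusted p = 0.219), cholesterol synthesis (0.0553), unfolded protein response (0.0544), immediate early and heat shock genes (0.0552), hypoxia (0.101), cell cycle (0.0512) and nuclear-retained RNA (0.608). With a library left out, some of them were called: corticosteroid-responsive genes higher in 3 tests without losartan library 1 and lower in 6 without losartan library 2, and unfolded protein response genes lower in 5 without untreated library 1, higher in 2 without losartan library 1 and lower in 4 without losartan library 2. Immediate early and heat shock genes gave 1 higher and 4 lower calls without untreated library 1, 2 higher without untreated library 2, 3 lower without losartan library 1, and 3 higher and 1 lower without losartan library 2. Cholesterol synthesis was higher in 1 test without untreated library 1, in 1 without losartan library 2 and in 1 with no composition factor, and cell cycle genes were lower in 2, 1 and 1 without untreated library 1, losartan library 1 and losartan library 2. A replicate block gave 1 higher and 1 lower call for the immediate early list and 1 lower call for the cell cycle list. Across 26 lists, 142 of 307 tests were called by camera, 95 higher and 47 lower. With an estimated correlation 0 were called, the smallest adjusted p being 0.195, and fry called 1. In simulated data with 1 changed list, camera at the preset correlation called it, and camera with an estimated correlation did not. The simulated genes varied independently, which favours the preset value, so this does not decide between the settings for the measured libraries.

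The last question was whether losartan acts differently in the proximal tubule and the thick ascending limb. Anks1b, a synaptic adaptor gene, differed most, by a log2 of 3.35 (adjusted p = 0.00249), with 14.7 and 75 CPM in the proximal tubule (log2 2.36) and 24.5 and 11.8 CPM in the thick ascending limb (-1.07). Ano4, a calcium-activated channel gene, differed by -2.18 (adjusted p = 0.0180; -1.75 and 0.39) and Uroc1 by -1.96 (adjusted p = 0.0463; -1.63 and 0.31). Segments of the proximal tubule were not tested apart against the thick ascending limb. The interaction test called 3 of 15325 genes, with 1505 at an unadjusted p under 0.05. Without losartan library 1 no gene was called, with adjusted p of 0.108, 0.448 and 0.510 for Anks1b, Ano4 and Uroc1. Without losartan library 2 the calls for Ano4 (adjusted p = 0.0672) and Uroc1 (adjusted p = 0.173) were lost. By contrast, 473 and 98 genes were called without untreated library 1 and untreated library 2.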

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

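The tests of free RNA and of doublets by class, of the sex of the untreated kidneys, of losartan library 1 alone, of class mix for inflammation genes, of less free RNA and of proximal tubule segments apart were chosen only after the result was seen, as was leaving libraries out of the test between classes.

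The effect of losartan differed between proximal tubule and thick ascending limb, by a test of the difference itself, for 3 genes. The difference in log2 change was 3.35 for Anks1b, -2.18 for Ano4 and -1.96 for Uroc1. Within proximal tubule nuclei Uroc1 had -0.54 in S1/S2, -1.05 in S3 and -1.77 in nuclei of neither segment. Its level in the proximal tubule was 17.8% of that in the distal convoluted tubule. Segments were not tested against the thick ascending limb, so a different mix of segments stays open for Uroc1. None of the 3 was called without losartan library 1 (adjusted p of 0.108, 0.448 and 0.510), and without losartan library 2 the adjusted p was 0.0364, 0.0672 and 0.173.

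Proximal tubule transcripts were higher with losartan in other classes, with a median log2 change of 0.54. More free RNA of every source, at an unchanged make-up, is argued against in endothelium, fibroblasts, intercalated cells, podocytes and thin limb. These classes were grouped after their values were seen. There, without nuclei above 5% proximal tubule UMIs, the median of thick ascending limb genes was at most 14.7% of that of proximal tubule genes. Free RNA of a changed make-up is not tested by this. In the whole kidney, thick ascending limb genes had a median of -0.14 (set tested in endothelium). Doublets are argued against in the 8 classes with few such nuclei. They kept at least 78.7% of their median without those nuclei or the richest 10%. The 8 classes were picked for few nuclei above 5%, so only leaving out the richest 10% counts here. More free RNA of every source stays open in macrophages and mural nuclei (at least 91.7%) and is undecided in principal and connecting tubule and parietal epithelium (at most 49.7%), where 50%, the bound set, lies within 2 standard errors over genes. Doublets stay open in intercalated, mural and macrophage nuclei, where without nuclei above 5% the median went from 1.63 to 0.46, from 0.98 to 0.50 and from 0.79 to 0.42, and the mural calls from 32 to 6; without the richest 10% the medians were 1.2, 1.12 and 0.39, and this decides nothing in mural and intercalated nuclei, as more than 10% of losartan library 1 lies above 5% (21.3% and 22.3%). Free RNA whose make-up follows the whole kidney stays open too. Across genes, the median Pearson r between the changes in a class and in the whole kidney was 0.711, at medians of 0.54 and 0.65. The genes are not independent, and whole-kidney sums include the nuclei of the class, so some correlation is built in and r decides nothing. The higher calls on these genes may reflect RNA from proximal tubule nuclei, and an effect of losartan within each class was not tested apart from it.

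Male-type genes of the proximal tubule were higher with losartan, with a median log2 change of 1.23 over 5 genes, none of them called alone. Female kidneys among the untreated are argued against, as the lowest untreated Y-linked level was 99.6% of the lowest losartan level. Another mix of segments is argued against by a median of 1.23 within S1/S2 nuclei (1.19 within S3), and losartan library 1 alone by a median of 1.03 without it (1.5 without losartan library 2). A candidate explanation is that losartan, or another difference between these 4 libraries such as androgen level of the mice, raises these transcripts. Nothing here tests one against the other.

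Injury and inflammation transcripts were lower with losartan in the whole kidney, with medians of -1.06 and -0.88 on log2 CPM. At the mean class mix the injury median was -0.60, 56.6% of its size (52.2% to 69.7% with each library left out). The shares of nuclei alone thus do not account for the whole fall. Class sums also hold free RNA, which may follow the mix of the library, so the mix as the whole cause stays open. The inflammation median was -0.38, 43.5% of its size (39.4% to 58.8% with each library left out), so class mix and change within classes cannot be told apart there, the range lying on both sides of the bound set. Less free RNA cannot be told apart from a change within classes. Each injury gene was taken in the tested class, other than the proximal tubule, with its highest losartan level. There 11 of 14 were lower, and the median log2 change beyond the loss of all free RNA was -0.071 (SE 0.21). Injured proximal tubule and urothelium, where Il34 and Spp1 had their highest levels, were not among these classes. The check thus leaves out classes with the highest levels of such genes. An effect of losartan on injury stays open.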

How the results depend on the processing

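A common doublet rate, an upper limit of 10000 UMIs, clustering without the called genes, the proximal tubule left out of the total, segments apart, left-out genes or nuclei rich in proximal tubule RNA, and libraries left out of the test between classes were tests chosen only after the result was seen. In the whole kidney DESeq2 called 1227 genes and a replicate block 1452 in place of 0, and with each library left out 0 to 22. The block rests on library numbers that no label pairs. Across genes in the whole kidney, the difference between untreated libraries 1 and 2 correlated with that between losartan libraries 1 and 2 (r = 0.43). The main model has no block and leaves this shared part in its spread. In the classes, where edgeR made 151 calls, DESeq2 made 884 (137 shared), no filter except a count of 1 3297, a replicate block 3048, doublets kept 1381 (112 shared, over 11 classes without principal and connecting tubule, 853 of them in intercalated cells), nuclei thinned to 1000 UMIs 262 (85 shared), genes centred within libraries 264, and resolution 0.5 78. A common doublet rate gave 364 calls and clustering without the called genes 296. With each library left out the calls ranged from 120 to 4023, of which 41 and 149 were shared. Over all classes the other settings stayed within 1.5 times: no mitochondrial limit 123, a 5% limit 201, mean CPM of at least 10 161, no composition factor 185, upper quartile 164, resolution 2 118, left-out genes 187, the UMI limit 168, and nuclei or genes rich in proximal tubule RNA left out 101 to 148. Single classes moved further: the 32 mural calls went to 0 at resolution 2, with the UMI limit, and without the 10% of nuclei richest in proximal tubule RNA or genes higher in the proximal tubule, to 5 at resolution 0.5 and to 9 with no mitochondrial limit, the 54 of the thick ascending limb to 24 at resolution 2 and 23 at resolution 0.5, the 16 of podocytes to 2 without those 10% of nuclei, and the 34 of the distal convoluted tubule to 15 with no mitochondrial limit. The 12 of principal and connecting tubule went to 58 with the UMI limit, 47 with a 5% limit and 30 with left-out genes, and those of podocytes to 37 with no composition factor. Of the 142 list calls 0 held with an estimated correlation and 1 with fry, and 72 of 216 tests were called without genes at a higher level in the proximal tubule; a block gave 150, no composition factor 144 and left-out libraries 121 to 161. Of 3 genes that differed between classes 1 remained at a mean CPM of at least 10 and 0 without a library block, and left-out libraries gave 0 to 473. Left-out libraries turned 3 list calls into calls on the other side, from lowest to highest median: mitochondrially encoded genes in the distal convoluted tubule (-0.30 to 1.23), ribosomal proteins in endothelium (-0.17 to 0.85) and in the thin limb (-1.18 to 0.49). Among named genes, 11331 of 12416 values kept direction and side of the threshold, and 2034 of 2566 with a library left out. Class shares had 0 calls in every setting. A limit of 1000 UMIs removed 0 nuclei and tests nothing. The causes of these changes were not tested. In simulated data a log2 change of 1 was found for 6.32% (macrophages) to 91% (proximal tubule) of genes in a class, and 0.847% to 15.9% of simulated calls in a class fell on unchanged genes, the most in the proximal tubule. The simulated genes varied independently, so these percentages do not carry over to the measured calls.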

Other observations

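No test in this part was chosen after the result was seen, except the segments of the proximal tubule taken apart and the genes at a higher level in the proximal tubule left out.

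Clock genes were called as a list in part of the tests, and in none with an estimated correlation. The circadian list rose in podocytes, with a median log2 change of 0.58 (adjusted p = 1.18e-05; adjusted p = 0.233 with an estimated correlation) and 4 of 14 members higher adjusted over the list alone and 0 over all genes. Tef and Rora, both transcription factors of the clock, stood at 0.78 and 0.80, Per3 at 1.02 and Nr1d2 at 0.62. In the whole kidney the list rose by 0.27 (adjusted p = 0.0235; adjusted p = 0.630 with an estimated correlation), with Ciart at 1.32, Tef at 0.75 and Npas2 at -1.2, and the call was lost without untreated library 2 (0.15, adjusted p = 0.419) and losartan library 2 (adjusted p = 0.0518). It was called in 6 of 13 tests, and in 2 without untreated library 2, 3 without losartan library 2 and 4 without losartan library 1. Without genes at a higher level in the proximal tubule it was called in 3 of 12 tests, and the podocyte median was 0.38 (adjusted p = 0.0183). In podocytes the median of proximal tubule genes was 0.68. The hour at which the kidneys were taken is not given in the sources used here.

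Respiratory genes of the mitochondrial genome rose in mural and mesangial nuclei, with a median of 0.91 (adjusted p = 5.95e-14; adjusted p = 0.358 with an estimated correlation). There 10 of 11 members were higher adjusted over the list alone and 1 over all genes, mt-Co2 (1.11, adjusted p = 0.0494; 0.0554 without losartan library 1). The list also rose in endothelium (0.79), thick ascending limb (0.46), fibroblasts (0.44) and distal convoluted tubule (0.22), with adjusted p of 0.416, 0.573, 0.491 and 0.787 with an estimated correlation. These medians moved with untreated library 1: without it they were 0.42, -0.03 (adjusted p = 0.842), 0.20 (adjusted p = 0.109) and -0.30, and without untreated library 2 they were 1.28, 1.11, 0.81 and 1.23. Over all 13 tests the list was called higher in 5 and lower in 0, against 2 and 5 without untreated library 1, and 13 and 0 without untreated library 2. Without losartan library 2 the fibroblast median was 0.27 and that of the distal convoluted tubule 0.08 (adjusted p = 0.232), and without losartan library 1 the latter was 0.38. Median mitochondrial percentages of kept nuclei were 0.0999 and 0.229 in untreated and 0.173 and 0.269 in losartan libraries. Nuclear-encoded respiratory genes rose in the whole kidney by 0.13 (adjusted p = 0.0321; adjusted p = 0.482 with an estimated correlation), with no call without untreated library 1 (adjusted p = 0.202) or losartan library 2 (adjusted p = 0.108). Oxidative stress response genes rose in the whole kidney by 0.27 (adjusted p = 0.0229; adjusted p = 0.620 with an estimated correlation), with Sod2 at 0.45, Prdx1 at 0.34 and Slc7a11 at -1.24, and no call without untreated library 2 (0.15, adjusted p = 0.397). Cytosolic ribosomal protein genes fell in the whole kidney by a median of -0.30 (adjusted p = 0.0229; adjusted p = 0.786 with an estimated correlation), with no call without untreated library 2 (0.03, adjusted p = 0.599) or losartan library 1 (-0.17, adjusted p = 0.301) and -0.56 and -0.47 without untreated library 1 and losartan library 2. Over 13 tests the ribosomal list was called higher in 2 and lower in 5 (smallest adjusted p = 0.601 with an estimated correlation), against 0 and 11 without untreated library 1, and 9 and 0 without untreated library 2. Sodium and water transport genes rose in macrophages and dendritic cells (0.39) and parietal epithelium (0.28), with adjusted p of 0.601 and 0.442 with an estimated correlation. In macrophages and dendritic cells thick ascending limb and proximal tubule genes also had medians above 0 (0.63 and 0.79). The first call was lost without losartan library 2 (adjusted p = 0.137), its median being 0.68 without losartan library 1 and 0.83 without untreated library 1, and the second without untreated library 2 (adjusted p = 0.481) and losartan library 1 (0.12, adjusted p = 0.0535), its median being 0.17 without losartan library 2.

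Some nuclei stand outside the named classes. An unnamed cluster held 0.350 ± 0.164% of untreated and 2.39 ± 1.35% of losartan nuclei (n = 2, log2 2.77, adjusted p = 0.243 by edgeR). The principal cell cluster held 8 of 8374 nuclei in untreated library 1 (0.0955%, 95% Clopper-Pearson interval 0.0413 to 0.188) and 315 of 8993 in untreated library 2 (3.50%, interval 3.13 to 3.90), and another unnamed cluster 4 and 252. With segments of the proximal tubule apart, edgeR called 6 of 12090 genes in S3 nuclei, 2 higher and 4 lower, 0 of 14043 in S1/S2 nuclei (1676 at an unadjusted p under 0.05) and 0 of 12017 in proximal tubule nuclei of neither segment (1148 at an unadjusted p under 0.05); DESeq2 was not run on segments.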
